A study of Mus musculus with 8 samples.

How the data were processed

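Total RNA from mouse liver was measured on 8 oligonucleotide arrays, with 2 arrays in each of 4 groups: wild-type females, knockout females, wild-type males and knockout males. Per the labels, the knockout mice lack Nrf2, were taken at 5 months of age, and came with their wild-type littermates from interbred heterozygotes of a cross between C57B6/SJL wild-type and C57B6/129SVJ knockout mice. The labels also mention spleen RNA, which was not analysed here.

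The deposited values are intensity per probe set on a linear scale. Their 2% trimmed means lay between 2502.3 and 2502.6 on the 8 arrays, so the deposited intensity values had been scaled to a common level, and they were used without further scaling. The software and the scaling steps that made them are not given in the sources used here. The arrays' number limits the precision of every comparison.

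The table held 12488 probe sets, of which 66 control probe sets were left out. Of the other 12422, 10833 carried 1 gene symbol, 396 carried several and 1193 carried none. Genes were named only from probe sets with 1 symbol. Symbols came from the array annotation, and 10817 of the 10833 probe sets could be matched to the gene annotation by gene identifier, with 0 symbols changed by it. Chromosomes were read from the annotation of the mouse reference genome C57BL/6J. Names that end in _f_at, _s_at, _g_at, _r_at or _i_at mark probe sets that may bind transcripts of related genes. Such probe sets are not marked at every gene below: those of Nqo1, Tubb2a, Eif2s3y and Alas2 are also of this kind.

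Values below a floor of 123.2, the 20th percentile of the whole table, were set to the floor, and log2 was taken. A probe set was kept when it exceeded the floor on at least 2 of the 8 arrays. This kept 11134 probe sets for 7692 named genes and left out 1288. Each gene was represented by its probe set with the highest mean log2 value over the 8 arrays.

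A model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend in the variance. It had 4 residual degrees of freedom and a prior worth 4.92. The contrasts were knockout against wild type averaged over both sexes, in females and in males, the male minus the female genotype effect, male against female averaged over both genotypes, and male against female in wild type. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all probe sets kept, with a threshold of 0.05. Some fold sizes are given with the log2 difference and its standard error, and others without them. A fold is taken from the difference of mean log2 values, with arrays below the floor set to it, so it differs from the ratio of mean intensities and depends on the floor where arrays lie below it. Differences are knockout minus wild type, or male minus female. Nothing in the labels says that the arrays come from separate animals, so the p-values measure the spread between arrays, which may be technical.

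Gene lists for liver pathways and for 12 kinds of cells, 41 lists in all, were fixed before the data were examined, as were the model, the threshold, the floor, the rule for named genes and the alternatives except those named in the closing section as chosen after seeing the data. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 41 lists of a contrast. Camera compares a list with all other genes. The alternatives were camera with a correlation estimated from the arrays, and fry, which tests whether a list's genes move on balance in one direction without comparing them with other genes. Members past the threshold were counted over all probe sets tested and adjusted over the list alone. Lists share members: 30 of the 32 measured genes of the Nrf2 target list and 10 of the 18 measured female-biased genes are also in another list.

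The rule for named genes took, for the average over both sexes, the 12 highest and 12 lowest fold changes among genes past the threshold whose knockout arrays all lay on one side of both wild-type arrays of their sex, filled to 10 in each direction by smallest p. For each sex and for the difference between the sexes it took 6 in each direction, filled to 3, and for male against female 10 in each direction. It added up to 4 members of every list with the smallest p, and 18 genes named in advance: Nfe2l2, Keap1, classical Nrf2 targets and genes of the X and Y chromosomes. Other genes named in the text were chosen after their values were seen, and are marked.

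The alternatives were quantile normalization, arrays scaled to one median or one 75th percentile, floors at the 10th and the 40th percentile, a pseudocount in place of the floor, no filter, only the probe sets above the median level, no intensity trend, robust variance, array weights, a threshold of 0.1, an additive model, genotype alone, the arrays of a single sex, the replicate number as a block, the mean of a gene's probe sets for the list tests, and leaving out each array in turn. The code was tested on simulated data with 200 changed probe sets of 11134 in each of 10 runs. For the genotype contrast over both sexes it recovered 36.8% of changes of log2 1 and 86.9% of changes of log2 2, with 5.14% of calls false. In males alone it recovered 11.9% and 51.4%, with 4.67% of calls false. For the difference between the sexes it recovered 1.4% and 27.3%, with 8.01% of calls false. A shift of -0.5 put on a list was found in 20 of 20 runs, with 2 lists called that shared no gene with it. The simulated genes varied independently, so these runs do not show how camera behaves where the genes of a list vary together.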

Results

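Liver expression was compared between mice that lack Nrf2, a transcription factor that switches on detoxification and antioxidant genes, and their wild-type littermates, in both sexes at 5 months of age. Each of the 4 groups had 2 arrays. Median intensity ran from 659.8 to 735.8 across the 8 arrays, and 77.8% to 82.0% of the probe sets on an array exceeded the floor. As the floor is a percentile of the whole table, that share is largely set by construction and does not measure detection. The ratio of 3' to 5' signal, a sign of RNA quality, ran from 1.43 to 3.76 for Gapdh and from 2.53 to 9.20 for actin, and wild-type female 1 had the highest value of both. Wild-type male 1 stood apart by immune transcripts: its intensity was 36573 for Ubd, a ubiquitin-like gene induced by interferon, against at most 2059 on the other arrays. The 2059 was that of wild-type male 2, and the remaining arrays lay between 41.5 and 330. Wild-type male 1 had 17222 for Cxcl13, a chemokine that attracts B cells, against at most 3019 on the other arrays (both genes chosen after their values were seen). Correlations between arrays of a group were 0.946 to 0.961, and those between groups 0.930 to 0.971. The first principal component held 25.2% of the variance and separated the sexes.

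Nfe2l2, which encodes Nrf2, was low in every knockout array. Its intensity was 6479.6 and 4861 in wild-type females, 265 and 197 in knockout females, 5854 and 6268 in wild-type males, and 583 and 57.9 in knockout males, the last below the floor. The mean was 5866 ± 718 (SD, n = 4) in wild type and 276 ± 222 (SD, n = 4) in knockout. The part of the transcript that its probe set reads, and whether the deletion covers that part, were not checked. The labels of sex fitted the X and Y genes: Xist, the RNA of the inactive X chromosome, lay between 1837 and 6199 on the female arrays and between 45.7 and 227 on the male arrays. Eif2s3y, a Y-linked translation factor gene, lay between 40.7 and 199 on the female arrays and between 2125 and 3125 on the male arrays.

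Averaged over both sexes, the comparison of knockout with wild type asks which liver transcripts depend on Nrf2. Abcc3, Aox1, Gstm3 and Ephx1, members of the fixed list of Nrf2 targets, fell in the knockout. Abcc3, which exports conjugated bile acids and drugs into the blood, was 3.28-fold lower (log2 -1.71 ± 0.15 SE, adjusted p = 0.00857, n = 4 per genotype), and Aox1, an aldehyde oxidase, was also 3.28-fold lower (log2 -1.71 ± 0.15, adjusted p = 0.00857). Gstm3, a glutathione S-transferase read from a family probe set, was 3.40-fold lower (log2 -1.76 ± 0.20, adjusted p = 0.0169), and Ephx1, the microsomal epoxide hydrolase, 2.30-fold lower (log2 -1.20 ± 0.15, adjusted p = 0.0287). On the other probe set of Gstm3 the genotypes overlapped, with intensities of 8334 to 17119 in wild type and 4226 to 8780 in knockout. Cyp2b9, a female-biased cytochrome P450, fell 3.66-fold (log2 -1.87 ± 0.20, adjusted p = 0.0132, with knockout male 1 set to the floor). Its log2 difference ran from -2.14 to -1.08 over the alternatives and depends on the floor, since it did not pass with the floor at the 40th percentile, where it was smallest in size.

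Nfe2l2 itself was 23.6-fold lower (log2 -4.56 ± 0.43, adjusted p = 0.00944), with knockout male 2 set to the floor. As its probe set was not placed on the transcript, this fold does not tell a deleted part from a lower transcript level. Gdpd3, a lysophospholipase gene, was 3.69-fold lower (adjusted p = 0.0116), and Bag3, a co-chaperone, 2.37-fold lower (adjusted p = 0.0247, family probe set). Ctsc, a lysosomal protease, fell by 2.01 on the log2 scale (adjusted p = 0.0169) on a probe set that is not the gene's brightest, while the brightest gave -0.19 and another -2.10. Ctsc was chosen after its values were seen. The genes that rose were Prm1, a protamine that packs DNA in sperm, at 11.2-fold (log2 3.49 ± 0.40, adjusted p = 0.0169), and Dynll1, a dynein light chain, at 1.83-fold (log2 0.87 ± 0.11, adjusted p = 0.0287), both read from family probe sets. The intensity of Prm1 was 148 to 443 in wild type and 1935 to 3605.5 in knockout. In limma, 11 of 11134 probe sets passed, 2 higher and 9 lower. An unadjusted p under 0.05 was found for 855 (7.68%), where a share of 0.05 is expected without any difference. With no filter on dim probe sets 17 passed, 9 higher and 8 lower.

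Other classical Nrf2 targets did not pass. Gstm1 gave log2 -1.15 (adjusted p = 0.0536), Ces1g, a carboxylesterase, -1.99 (adjusted p = 0.0547), Me1, the NADPH-producing malic enzyme, -0.96 (adjusted p = 0.1), and Nqo1, the quinone reductase, -1.41 (adjusted p = 0.321). The value of Gstm1 came from a family probe set. Its other probe set lay between 2463 and 4641 in wild type and between 2769 and 3560 in knockout. Gclc, the catalytic subunit of glutathione synthesis, gave -0.72 (adjusted p = 0.247), and its partner Gclm -0.00 (adjusted p = 0.998). Gsta2 gave -0.73, Gsta3 -0.75, Gsta4 -0.55, Hmox1 -0.52 and Txnrd1 -0.28, with adjusted p from 0.247 to 0.746. Keap1, the repressor of Nrf2, lay between 290.4 and 468 in wild type and between 87.5 and 397 in knockout (adjusted p = 0.618). Gsta1 was below the floor, and no probe set carried Ddx3y as its 1 symbol. Oat, ornithine aminotransferase, was not past the threshold either (adjusted p = 0.0532), and its 2 probe sets differed in sign. The other genes nearest to the threshold among those higher in knockout, none of them past it, were Klk1b16 (log2 1.76), Hmgcs1 (0.87), Il1r1 (1.67), Znrf4 (1.78), Ddc (0.81), Sprr2f (1.52), Idi1 (1.01) and Saa-ps (1.97), with adjusted p from 0.107 to 0.21.

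The count of 11 fell to 0 without wild-type female 1, wild-type female 2, knockout female 1 or knockout female 2. It fell to 3 without knockout male 1, to 4 without wild-type male 1 and to 2 without knockout male 2, and rose to 22 without wild-type male 2. With wild-type female 1 and wild-type male 1 both left out it was 0, and it was 0 without the intensity trend, 5 with an additive model, 4 with genotype alone and 25 with a pseudocount. Of the fits that left out 1 array, Abcc3 passed in 4, Nfe2l2 in 3, Aox1, Cyp2b9 and Prm1 in 2, Gdpd3 and Gstm3 in 1, and Ephx1, Bag3 and Dynll1 in 0.

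**Figure D1:**
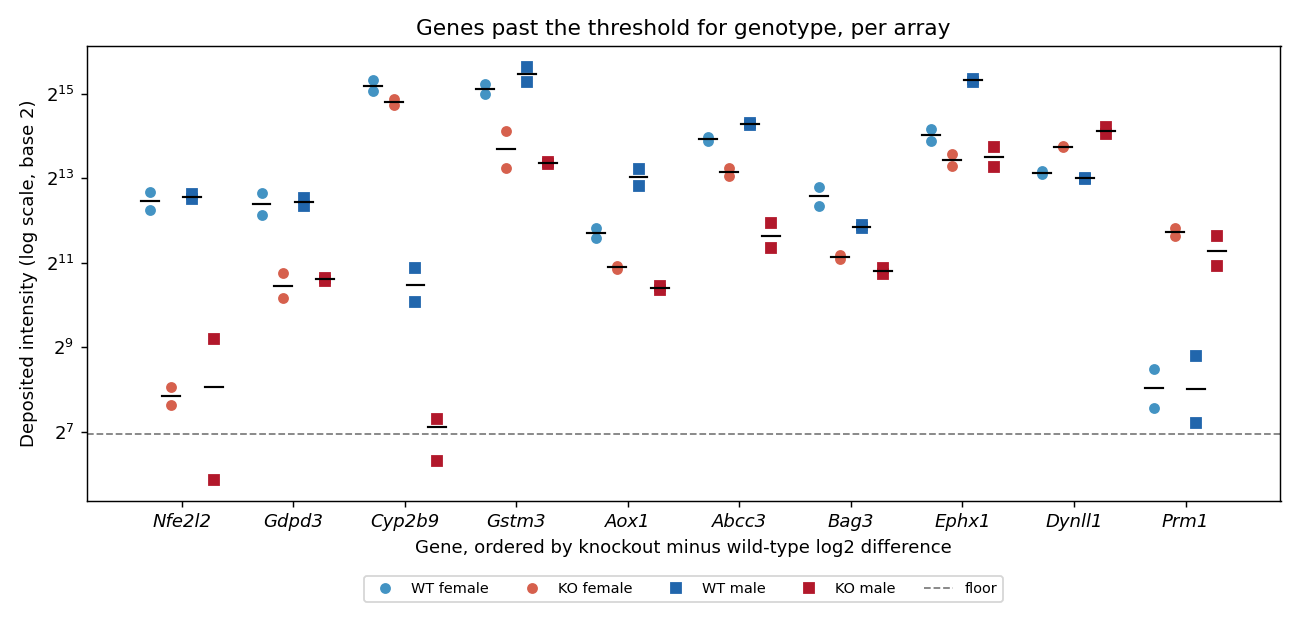
Deposited intensity on a log2 axis of genes past the threshold for genotype, 1 point per array, with the 4 groups in separate colours, the floor as a dashed line and a bar at each group's mean log2 value, values below the floor being set to it. The 4 knockout arrays of Nfe2l2 sit between 57.9 and 583 in intensity, all below the wild-type arrays, and those of Prm1 sit between 1935 and 3605.5, all above them.

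Among the fixed lists, the Nrf2 targets fell as a group. Of 32 measured genes, 4 were lower over all genes tested (Abcc3, Aox1, Gstm3 and Ephx1) and 12 were lower adjusted over the list alone, with a median log2 difference of -0.35 (camera adjusted p = 1.38e-10; adjusted p = 0.0549 with an estimated correlation; fry adjusted p = 0.00155). Carbonyl and ester metabolism, which detoxifies aldehydes, ketones and esters, fell with a median of -0.28 over 20 genes, 2 of them lower over all genes tested and 5 adjusted over the list alone (adjusted p = 2.45e-06; adjusted p = 0.0998 with an estimated correlation; fry 0.0125). Cholesterol synthesis rose: 15 of its 16 genes had positive differences, with a median of 0.46 (adjusted p = 1.77e-10; adjusted p = 0.233 with an estimated correlation). In that list 0 genes passed over all genes tested in limma and 7 were higher adjusted over the list alone. Among them were Hmgcs1, which makes the precursor of mevalonate, Idi1, and Fdps, a prenyl transferase (log2 0.91). The list of glucuronosyltransferases and sulfotransferases, which also holds the sugar donor enzymes Ugdh and Ugp2, fell with a median of -0.25 over 10 genes (adjusted p = 0.00185; adjusted p = 0.297 with an estimated correlation), with 0 lower over all genes tested and 2 adjusted over the list alone, the transferase Ugt2b5 (-0.67) and Ugp2 (-0.58), which makes UDP-glucose and conjugates nothing itself. That call was lost without knockout female 1 (adjusted p = 0.187). Hepatic transporters fell with a median of -0.23 over 9 genes, 1 of them (Abcc3) lower over all genes tested and 3 adjusted over the list alone, with Abcg2 (-0.63) and Abcc6 (-0.70) (adjusted p = 0.00218; adjusted p = 0.284 with an estimated correlation).

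Cytochromes P450 of drug metabolism fell with a median of -0.13 over 21 genes, 1 of them (Cyp2b9) lower over all genes tested and 1 adjusted over the list alone (adjusted p = 0.0058; adjusted p = 0.297 with an estimated correlation). After quantile normalization the median was -0.03, and without wild-type male 2 they did not pass (adjusted p = 0.0615). Female-biased liver genes fell with a median of -0.33 over 18 genes, 1 lower over all genes tested and 2 adjusted over the list alone (adjusted p = 0.00532; adjusted p = 0.284 with an estimated correlation), lost without wild-type female 2 (0.0694) or knockout female 1 (0.273). Proteasome subunits rose with a median of 0.21, 24 of 31 of them positive and 0 past the threshold over all genes tested or adjusted over the list alone (adjusted p = 0.00245; adjusted p = 0.297 with an estimated correlation), lost without knockout male 1 (0.0717) or wild-type male 2 (0.0615).

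Immune and stromal lists fell as well. The interferon response had 30 of 31 genes with negative differences and a median of -0.33 (adjusted p = 1.56e-09; adjusted p = 0.233 with an estimated correlation). In limma, 0 genes passed over all genes tested and 1 adjusted over the list alone. Its members with the smallest p were Gbp3 (log2 -1.23), Igtp (-0.94), Ifit3 (-0.88) and Ifit1 (-1.29). Markers of T and NK cells had a median of -0.44 over 14 genes (adjusted p = 0.00185; adjusted p = 0.233 with an estimated correlation), with 0 lower over all genes tested and 2 adjusted over the list alone: Zap70, a T cell receptor kinase (-0.71, with 1 of its other 2 probe sets of opposite sign), and Klrd1, an NK cell receptor (-1.06). Markers of Kupffer cells and other macrophages had a median of -0.61 over 15 genes with 0 past the threshold in either count (adjusted p = 0.00023; adjusted p = 0.42 with an estimated correlation), and the call was lost without wild-type male 1 (adjusted p = 0.21), the array with the high Ubd and Cxcl13. Stellate cells and fibroblasts had a median of -0.24 over 18 genes (adjusted p = 0.00495; adjusted p = 0.233 with an estimated correlation), with 0 lower over all genes tested and 2 adjusted over the list alone, the matrix genes Dcn (-0.76) and Col4a1 (-1.08).

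Markers of blood vessel lining, inflammation, antigen presentation and the acute phase passed too, each with calls that rest on single arrays. Endothelial markers had a median of -0.37 over 13 genes (adjusted p = 0.0241; adjusted p = 0.297 with an estimated correlation), lost without knockout female 1 (0.067) or wild-type male 2 (0.1). Inflammation and cell adhesion had a median of -0.32 over 20 genes (adjusted p = 0.0309; adjusted p = 0.297 with an estimated correlation), with 2 lower adjusted over the list alone, the chemokines Cxcl13 (-2.91) and Ccl2 (-1.95). Its call was lost without wild-type female 2 (0.0915), knockout female 1 (0.064), knockout male 1 (0.0909) or wild-type male 1 (0.131). Antigen presentation had a median of -0.25 over 18 genes (adjusted p = 0.0317; adjusted p = 0.429 with an estimated correlation). It did not pass without wild-type female 2 (0.372), knockout female 1 (0.064), knockout female 2 (0.0543), knockout male 1 (0.32) or wild-type male 1 (0.264), nor with quantile normalization (0.0995). The acute phase list had a median of 0.23 over 27 genes (adjusted p = 0.0323; adjusted p = 0.314 with an estimated correlation). Its call ended without wild-type female 1 (0.109), knockout female 2 (0.0583), knockout male 1 (0.239) or wild-type male 2 (0.452). In these lists 0 genes passed over all genes tested, and outside inflammation 0 adjusted over the list alone. Of the 41 lists, 16 passed with camera, 0 with an estimated correlation and 2 with fry, and none of the 16 changed direction with quantile, median or 75th percentile scaling.

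In females, the comparison asks the same question within 1 sex, with n = 2 arrays per group. No probe set passed. Among the genes with the smallest p-values, Nfe2l2 gave log2 -4.62 ± 0.61 (24.5-fold, adjusted p = 0.203), Gdpd3 -1.93 ± 0.27 (3.81-fold, adjusted p = 0.203) and Bag3 -1.44 ± 0.22 (2.71-fold, adjusted p = 0.254). On the upper side, Prm1 gave 3.70 ± 0.57 (adjusted p = 0.254), Bik, a gene of programmed cell death, 2.69 ± 0.53 (adjusted p = 0.711), and Mgst1, a microsomal glutathione transferase, 1.07 ± 0.23 (adjusted p = 0.711). The smallest adjusted p belonged to Ctsc (log2 -2.96, adjusted p = 0.0947, chosen after its values were seen).

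As a group, fatty acid oxidation and PPARalpha targets rose in knockout females, with positive differences in 21 of 28 genes and a median of 0.31 (camera adjusted p = 0.000133; adjusted p = 0.548 with an estimated correlation); 0 passed over all genes tested or adjusted over the list alone. Its members with the smallest p were Cyp4a14, a fatty acid hydroxylase (log2 1.98), Cpt1a, the gatekeeper of mitochondrial oxidation (0.66), Hadh (0.60) and Eci1 (0.48). The Nrf2 targets fell with a median of -0.18 over 32 genes (adjusted p = 0.000133; adjusted p = 0.274 with an estimated correlation), with 0 lower over all genes tested and 4 adjusted over the list alone, Gstm3 (-1.43), Me1 (-0.96), Aox1 (-0.82) and Abcc3 (-0.79), and that call was lost without wild-type female 2 (adjusted p = 0.0806). Glucuronosyltransferases and sulfotransferases fell (median -0.35, adjusted p = 0.00382), lost without wild-type female 2 (0.194) or knockout female 1 (0.758), and proteasome subunits rose (median 0.25, adjusted p = 0.00382), lost without wild-type female 1 (0.0964). With an estimated correlation both had an adjusted p = 0.548. The interferon response fell (median -0.16, adjusted p = 0.0143; adjusted p = 0.584 with an estimated correlation), lost without wild-type female 2 or knockout female 1 (0.466 each). Female-biased genes fell (median -0.41, adjusted p = 0.0167; adjusted p = 0.548 with an estimated correlation). This did not hold without wild-type female 2 (0.478), knockout female 1 (0.689) or wild-type male 1 (0.0559). Fatty acid synthesis fell (median -0.31, adjusted p = 0.0399; adjusted p = 0.548 with an estimated correlation). The last of these ended without wild-type female 2 (0.525), knockout female 1 (0.503), knockout male 1 (0.0578), wild-type male 1 (0.0559) or knockout male 2 (0.0554), and with quantile normalization (0.0753) or the mean of a gene's probe sets (0.106). Of these last 5 lists 0 genes passed over all genes tested, and adjusted over the list alone 1 female-biased and 1 fatty acid synthesis gene were lower.

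In limma, 583 probe sets (5.24%) had an unadjusted p under 0.05 in females, near the share of 0.05 expected without any difference, and 0 passed. The count was 3 with a floor at the 40th percentile or a pseudocount, 4 without a filter, 2 with robust variance or only the probe sets above the median level, and 0 with the arrays of females alone. It was 1 without knockout male 1, wild-type male 1 or knockout male 2, and 2 without wild-type male 2. Of the 41 lists, 7 passed with camera, 0 with an estimated correlation and 0 with fry.

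In males, Abcc3, Aox1, Gstm3 and Ephx1 of the Nrf2 target list fell, and Hmgcs1 of the cholesterol synthesis list rose. Abcc3 was 6.23-fold lower (log2 -2.64 ± 0.21, adjusted p = 0.00306, n = 2 per group). Aox1 was lower 6.12-fold (log2 -2.61 ± 0.22, adjusted p = 0.00306), and Cyp2b9 10.2-fold (log2 -3.35 ± 0.28, adjusted p = 0.00306, with knockout male 1 set to the floor). The log2 difference of Cyp2b9 ran from -3.75 to -1.77 over the alternatives, and it did not pass with the floor at the 40th percentile, where it was smallest in size. Ces1g was 7.51-fold lower (adjusted p = 0.0433), Gstm3 4.28-fold (adjusted p = 0.0433), Ephx1 3.50-fold (adjusted p = 0.0346) and Nfe2l2 22.6-fold (adjusted p = 0.0433, with knockout male 2 set to the floor). The other probe set of Gstm3 read 17119 and 8722 in wild-type males against 8640 and 6336 in knockout males. Hmgcs1 rose 3.02-fold (log2 1.60 ± 0.22, adjusted p = 0.0433), and Dynll1 rose 2.19-fold (adjusted p = 0.0433). Ddc, which makes dopamine and serotonin, gave log2 1.43 (adjusted p = 0.0648).

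Oat fell by 1.54 on the log2 scale (adjusted p = 0.0425), but its other probe set gave 1.85. The other probe sets past the threshold were chosen after their values were seen. Nr1i3, which encodes the xenobiotic receptor CAR, fell by 1.50 (adjusted p = 0.0346), and its other 2 probe sets gave -1.41 and -1.06. Acaa1b, a peroxisomal thiolase, fell by 1.86 on one probe set (adjusted p = 0.0416) and gave -0.82 on its brightest. Pcp4l1 fell (log2 -3.90 or lower, adjusted p = 0.0416), with both knockout males below the floor, and gave -0.06 on its brightest probe set. Foxn3, a forkhead factor, rose by at least 2.46 (adjusted p = 0.0433) from wild-type arrays below the floor, while its brightest probe set gave -1.18.

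Cholesterol synthesis rose in knockout males, with 15 of 16 genes positive and a median of 0.98 (camera adjusted p = 7.92e-12; adjusted p = 0.181 with an estimated correlation; fry 0.0486). Of these, 1 was higher over all genes tested and 9 adjusted over the list alone, with Hmgcs1, Idi1 (log2 1.75), Cyp51 (1.40) and Msmo1 (1.21) first. Fatty acid oxidation and PPARalpha targets fell: 26 of 28 genes were negative, with a median of -0.44 (adjusted p = 8.5e-09; adjusted p = 0.249 with an estimated correlation), 0 lower over all genes tested and 3 adjusted over the list alone. The latter were Pex11a, a peroxisome proliferation factor (-1.21), Plin2, a lipid droplet coat protein (-1.12), and Vnn1, a pantetheinase (-2.42). The Nrf2 targets fell with a median of -0.54, 5 of 32 lower over all genes tested and 12 adjusted over the list alone (adjusted p = 7.94e-10; adjusted p = 0.0669 with an estimated correlation; fry 0.00159). Carbonyl and ester metabolism fell with a median of -0.46, 3 of 20 lower over all genes tested and 5 adjusted over the list alone (adjusted p = 3.19e-07; adjusted p = 0.0796 with an estimated correlation). Cytochromes P450 had a median of -0.30, 1 of 21 lower over all genes tested and 2 adjusted over the list alone (adjusted p = 0.000489; adjusted p = 0.282 with an estimated correlation). Transporters had a median of -0.40, 1 of 9 lower over all genes tested and 2 adjusted over the list alone (adjusted p = 0.00279; adjusted p = 0.282 with an estimated correlation), lost without wild-type male 2 (0.102). Glutathione S-transferases had a median of -0.26, 1 of 17 lower over all genes tested and 4 adjusted over the list alone (adjusted p = 0.0202; adjusted p = 0.489 with an estimated correlation), lost without knockout male 1 (0.369) or wild-type male 2 (0.517).

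The interferon response fell in knockout males with a median of -0.47 and 30 of 31 genes negative, 0 lower over all genes tested and 4 adjusted over the list alone (adjusted p = 1.22e-08; adjusted p = 0.277 with an estimated correlation). T and NK cell markers had a median of -0.61 (adjusted p = 0.000273; adjusted p = 0.185 with an estimated correlation; fry 0.0446). Macrophage markers had a median of -0.81 (adjusted p = 6.34e-05; adjusted p = 0.38 with an estimated correlation), lost without wild-type male 1 (0.594), the array with the high immune transcripts. Antigen presentation had a median of -0.38 (adjusted p = 0.00774; adjusted p = 0.38 with an estimated correlation), lost without knockout male 1 (0.285) or wild-type male 1 (0.169). Stellate markers had a median of -0.28 (adjusted p = 0.044; adjusted p = 0.318 with an estimated correlation). These markers did not pass without knockout female 1 (0.0616), knockout female 2 (0.0643), knockout male 1 (0.115), wild-type male 1 (0.226) or knockout male 2 (0.0698). In these 4 cell and antigen lists 0 genes passed over all genes tested, and 2 stellate genes, Dcn and Col4a1, were lower adjusted over the list alone.

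In limma, 14 probe sets passed in males, 3 higher and 11 lower, against 0 higher and 6 lower with arrays scaled to one median. With no filter on dim probe sets the balance turned, to 10 higher and 5 lower of 15. The count was 3 without wild-type female 1 or wild-type female 2, 5 without knockout female 1 or knockout female 2, 2 without knockout male 1, 7 without wild-type male 1 and 1 without knockout male 2. It was 0 without wild-type female 1 and wild-type male 1 together, 0 with the arrays of males alone and 0 without the intensity trend. Abcc3 passed in each of the 8 fits that left out 1 array, and Aox1 and Cyp2b9 in 6. Gstm3 passed in 2 of them, Nfe2l2 in 1, and Hmgcs1, Ces1g and Dynll1 in 0.

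**Figure D2:**
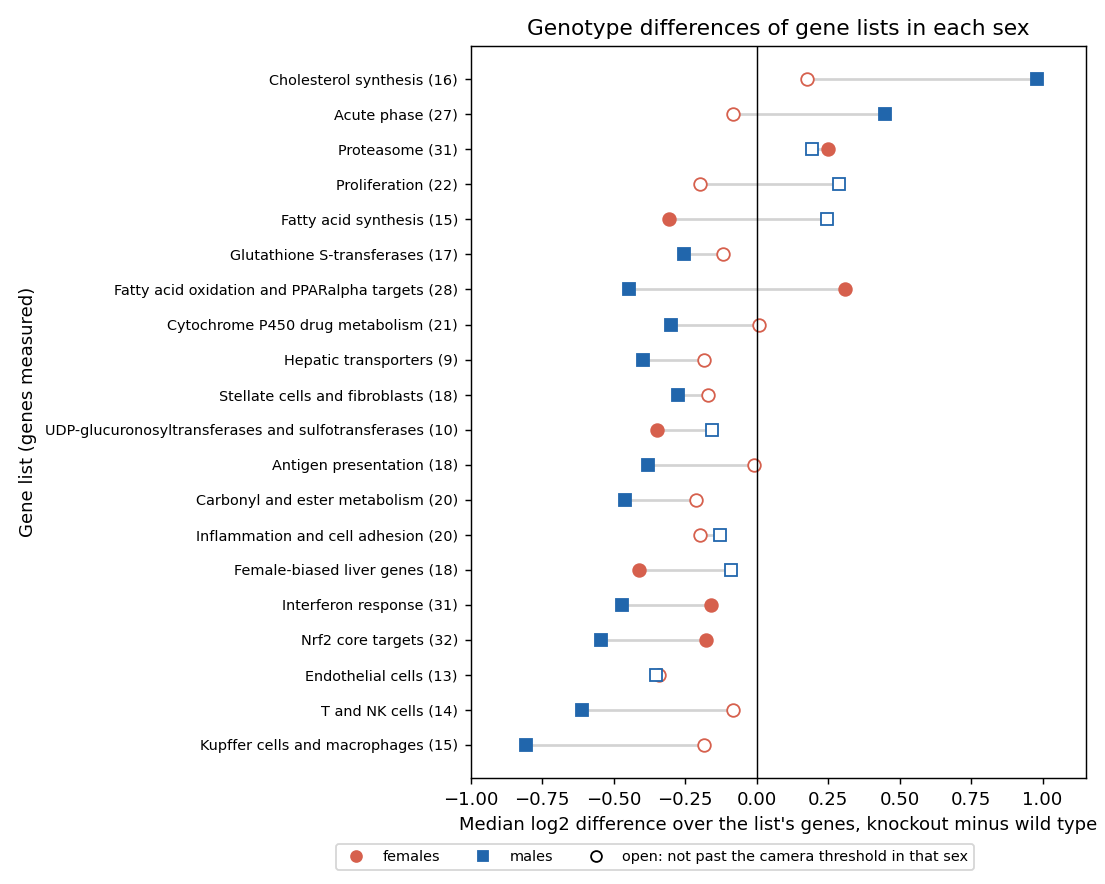
Median log2 difference, knockout minus wild type, of each gene list that passed with camera in at least 1 of the genotype contrasts, in females (circles) and males (squares), with the number of measured genes in brackets and open symbols where camera did not pass. Fatty acid oxidation sits at 0.31 in females and -0.44 in males.

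Whether the knockout acted differently in the sexes was tested as the male minus the female genotype effect. The fatty acid oxidation list had the smallest camera p at the preset correlation: the genotype effect was lower in males than in females for 26 of its 28 genes, with a median difference of -0.82 (camera adjusted p = 3.1e-13; adjusted p = 0.197 with an estimated correlation; fry 0.112). In it 0 genes passed over all genes tested and 10 were lower adjusted over the list alone, with Pex11a (log2 -1.26), Eci1 (-0.99), Vnn1 (-3.62) and Hadh (-1.07) first. The change of cholesterol synthesis was higher in males than in females, with a median difference of 0.86 over 16 genes (adjusted p = 2.53e-06; adjusted p = 0.391 with an estimated correlation), 0 past the threshold over all genes tested and 3 adjusted over the list alone, Hmgcs1 (1.45), Idi1 (1.49) and Cyp51 (1.37). In females alone this list did not pass (median 0.18, adjusted p = 0.13). The Nrf2 targets fell further in males (median -0.27, adjusted p = 0.00261), and the change of carbonyl and ester metabolism was lower there (median -0.41, adjusted p = 0.0018), though that list did not pass in females alone (median -0.21, adjusted p = 0.13). Both differences had an adjusted p = 0.197 with an estimated correlation and were lost without knockout female 2 (0.102 each). In each, 0 genes passed over all genes tested and 3 were lower adjusted over the list alone, Aox1 (-1.80) and Ephx1 (-1.22) in both.

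No single probe set passed this test. On the lower side the smallest p-values were those of Cyp2b9 (log2 -2.96 ± 0.40, adjusted p = 0.214), Bik (-4.75 ± 0.76, adjusted p = 0.312) and Abcc3 (-1.85 ± 0.30, adjusted p = 0.312). On the upper side they were those of Slc25a25, a mitochondrial carrier (2.47, adjusted p = 0.312), Ifna15, an interferon (2.93, adjusted p = 0.559, family probe set), and Grik5, a glutamate receptor subunit (3.01, adjusted p = 0.559, with another probe set of opposite sign). In limma, 674 probe sets (6.05%) had an unadjusted p under 0.05, little above the share of 0.05 expected without any difference. Of all probe sets 0 passed, with 8 past the threshold without a filter. Across the 7692 genes, which are not independent replicates, the female and male genotype effects correlated with Pearson r = 0.104 and Spearman rho = 0.0730. Of 11 genes called in males by their brightest probe set, 11 had the same direction in females, and 10 had a smaller fold there. These genes were picked for passing in males, so smaller folds in females are partly built in. They are no evidence that the sexes differ. For Hmgcs1 the female arrays overlapped, at 27149 and 37014 in knockout and 30107 and 27211 in wild type. Among the probe sets called in males that are not a gene's brightest, that of Pcp4l1 also fell in females. That of Acaa1b rose there, from a mean log2 of 12.84 in wild type to 13.72 in knockout.

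**Figure D3:**
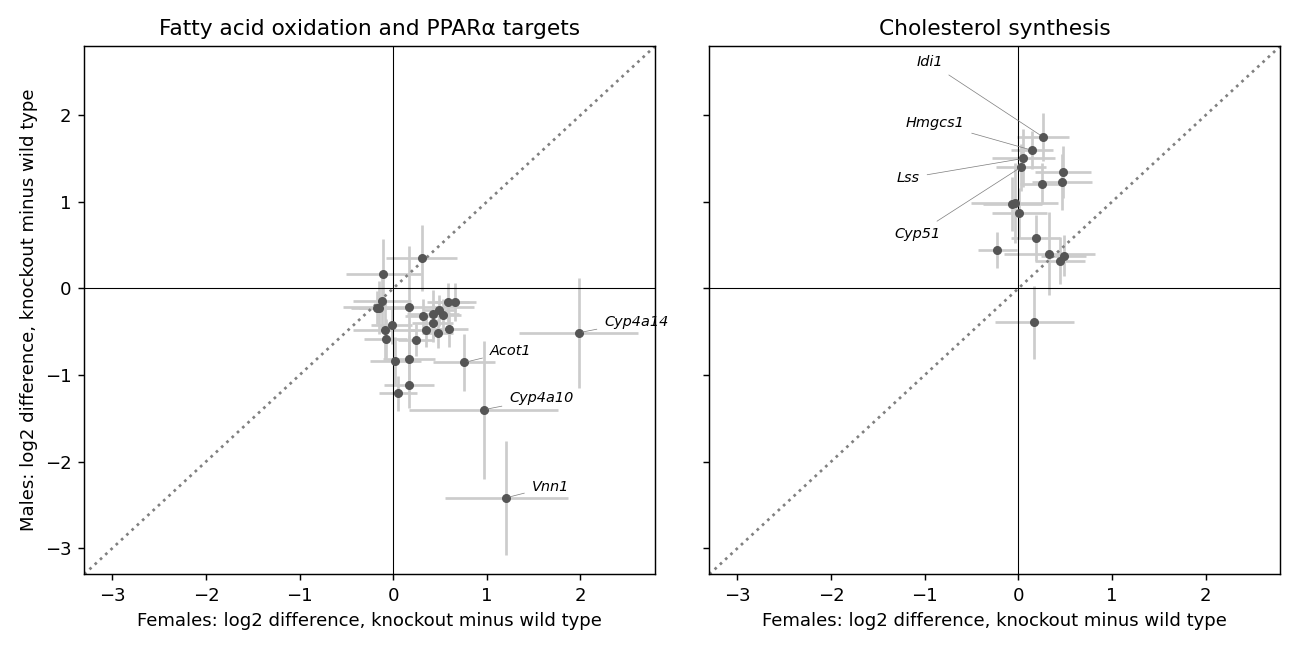
Log2 difference, knockout minus wild type, in females (horizontal axis) and in males (vertical axis) for each gene of 2 lists, with standard errors as bars and equality as the dotted line. Of the 28 fatty acid oxidation genes, 26 had a lower difference in males than in females, and of the 16 cholesterol synthesis genes, 13 had a higher one.

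The comparison of males with females, averaged over both genotypes, shows the sex difference of the liver. Sult2a2, a sulfotransferase, was 281-fold lower in males (log2 -8.14 ± 0.38, adjusted p = 1.06e-05, n = 4 per sex, with 1 of 4 male arrays at the floor). Sult3a1, another sulfotransferase, was at least 143-fold lower (log2 -7.16 ± 0.25, adjusted p = 1.53e-06, with 3 of 4 male arrays at the floor). Cyp2b13, a cytochrome P450, was at least 96.3-fold lower in males, with all male arrays at the floor (adjusted p = 1.53e-06). Cyp2b9 was 73.5-fold lower (adjusted p = 1.53e-06, with 1 of 4 male arrays at the floor). Hao2, a peroxisomal oxidase, was at least 98.7-fold lower (adjusted p = 1.23e-05, with 3 of 4 male arrays at the floor). Hsd3b5, a steroid dehydrogenase, was 35.8-fold higher in males (log2 5.16 ± 0.50, adjusted p = 0.00162), Cyp4a12b, a fatty acid hydroxylase, 19.0-fold (log2 4.25 ± 0.20, adjusted p = 1.06e-05), and Alas2, of heme synthesis, 8.43-fold (adjusted p = 3.11e-05).

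Gstp1, a glutathione S-transferase, was 4.96-fold higher in males (adjusted p = 0.000326), Etfbkmt, a methyltransferase, 4.23-fold (adjusted p = 0.000938), and Haus4, a spindle protein, at least 3.97-fold, with all female arrays at the floor (adjusted p = 0.0374). The serum amyloid genes Saa2 (log2 3.36, adjusted p = 0.00758), Saa-ps (3.32, adjusted p = 0.00611) and Saa3 (2.25, adjusted p = 0.0216) were higher in males, the first 2 on family probe sets. For Saa2 and Saa-ps the mean difference was larger in the knockout, but limma's test of the male minus female genotype effect passed for 0 probe sets. The wild-type male arrays of Saa2 lay far apart (84776 and 18793), and Saa-ps was below the floor in wild-type female 1 (82). Mean log2 of Saa2 was 12.88 and 15.28 in wild-type females and males, and 13.08 and 17.4 in knockout females and males. For Saa-ps these means were 7.16 and 9.20, and 7.85 and 12.45. Cyp4a14 (log2 -3.46), Prom1, a membrane glycoprotein (-3.05), Tubb2a, a tubulin (-2.39), and Cyp2c39 (-2.35) were lower in males, with adjusted p from 0.00487 to 0.0117. Xist was 19.9-fold lower in males (adjusted p = 0.000179, 1 of 4 male arrays at the floor) and Eif2s3y 18.0-fold higher (adjusted p = 0.000153, 2 of 4 female arrays at the floor), while Kdm5d, Y-linked, lay between 35.2 and 167 on all arrays (log2 0.11, adjusted p = 0.894).

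Female-biased liver genes, fixed as a list, were lower in males with a median of -1.90, 11 of 18 lower over all genes tested and 14 adjusted over the list alone (camera adjusted p = 3.23e-27; adjusted p = 0.0295 with an estimated correlation). Male-biased genes were higher with a median of 1.35, 6 of 12 over all genes tested and 10 adjusted over the list alone (adjusted p = 7.98e-16; adjusted p = 0.235 with an estimated correlation). Cholesterol synthesis was lower in males with a median of -0.78, 4 of 16 lower over all genes tested, Hmgcs1 (log2 -1.33), Mvd (-1.99), Idi1 (-1.17) and Fdft1 (-0.96), and 11 adjusted over the list alone (adjusted p = 1.34e-10; adjusted p = 0.235 with an estimated correlation). Fatty acid synthesis was lower with a median of -0.58, 3 of 15 lower over all genes tested, and 7 lower and 1 higher adjusted over the list alone (adjusted p = 3.58e-05; adjusted p = 0.371 with an estimated correlation), including Fasn, fatty acid synthase (-1.27). Glucuronosyltransferases and sulfotransferases (median -0.28, adjusted p = 0.000542; adjusted p = 0.48 with an estimated correlation) and the interferon response (median -0.28, adjusted p = 0.000603; adjusted p = 0.48 with an estimated correlation) were lower, the latter lost without wild-type male 2 (0.0513). The acute phase list was higher (median 0.17, adjusted p = 0.000627; adjusted p = 0.371 with an estimated correlation) but did not pass with quantile normalization (0.0982), and macrophage markers were lower (median -0.64, adjusted p = 0.00359; adjusted p = 0.528 with an estimated correlation), lost without knockout female 2 (0.0526) or wild-type male 2 (0.507). Over all genes tested, 2 of 10 genes of the glucuronosyltransferase and sulfotransferase list, 3 of 31 interferon genes and 1 of 15 macrophage markers were lower and 2 of 27 acute phase genes higher. Adjusted over the list alone these were 4, 5, 1 and 4. Cytochromes P450 of drug metabolism did not pass as a list (adjusted p = 0.191), with 5 of 21 genes lower and 0 higher over all genes tested. The median of that list was 0.103, and -0.125 after quantile normalization.

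In limma, 119 probe sets passed, 52 higher and 67 lower in males, for 103 named genes. The count was 40 without wild-type female 1, 32 without wild-type female 2, 51 without knockout female 1, 26 without knockout female 2, 30 without knockout male 1, 78 without wild-type male 1, 32 without knockout male 2, 69 without wild-type male 2, and 18 without wild-type female 1 and wild-type male 1 together. In each of the 8 fits that left out 1 array, 12 named genes passed: Sult2a2, Sult3a1, Cyp2b13, Cyp2b9, Hao2, Hsd3b5, Cyp4a12b, Alas2, Gstp1, Etfbkmt, Xist and Eif2s3y.

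Within wild type alone, the sex difference shows what these livers looked like without the knockout. Cholesterol synthesis was lower in wild-type males than in wild-type females, with a median of -1.15 over 16 genes, 2 of them lower over all genes tested and 11 adjusted over the list alone (camera adjusted p = 1.19e-13; adjusted p = 0.207 with an estimated correlation). Fatty acid oxidation was higher in wild-type males with a median of 0.42 over 28 genes, 0 past the threshold over all genes tested, 8 higher and 2 lower adjusted over the list alone (adjusted p = 0.000252; adjusted p = 0.452 with an estimated correlation). The Nrf2 targets were higher in wild-type males with a median of 0.24 over 32 genes, 1 of them higher over all genes tested, and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0197; adjusted p = 0.208 with an estimated correlation). Female-biased genes were lower with a median of -1.92, 6 of 18 over all genes tested and 13 adjusted over the list alone (adjusted p = 7.46e-23; adjusted p = 0.0414 with an estimated correlation). The acute phase (median 0.13, adjusted p = 0.188), the interferon response (-0.16, adjusted p = 0.308) and macrophage markers (-0.23, adjusted p = 0.577), which passed in the average over both genotypes, did not pass within wild type. These list tests within wild type were not repeated with arrays left out. In limma, 30 probe sets passed, 13 higher and 17 lower. The count was 12 without wild-type female 1, 16 without wild-type female 2, 18 without knockout male 1, 16 without wild-type male 1, 19 without knockout male 2, 16 without the intensity trend and 0 without wild-type female 1 and wild-type male 1 together.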

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

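The split counts and the test on the 200 measured genes around Nfe2l2 were planned before their results were seen; the other tests in this part, those of germ cell RNA, the targeting construct, called genes on chromosomes 2 and 7, wild-type male 1 and cell shares, were chosen only after the result was seen.

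The genotype effect differed between the sexes, by camera on the male minus female effect, in 10 gene lists. For fatty acid oxidation and PPARalpha targets the median difference was -0.82 (adjusted p = 3.1e-13), for cholesterol synthesis 0.86 (adjusted p = 2.53e-06), for carbonyl and ester metabolism -0.41 (adjusted p = 0.0018), and for Nrf2 targets -0.27 (adjusted p = 0.00261). Cytochromes P450 gave -0.53 (adjusted p = 0.0103), fatty acid synthesis 0.64 (adjusted p = 0.0196), proliferation 0.51 (adjusted p = 0.0196), the interferon response -0.36 (adjusted p = 0.0251), macrophage markers -0.62 (adjusted p = 0.0386) and the acute phase 0.27 (adjusted p = 0.0484). With an estimated correlation, 0 of the 10 passed, with adjusted p from 0.197 to 0.747. Leaving out 1 array kept the first pair of lists in each of the 8 fits. Carbonyl metabolism and Nrf2 targets were lost without knockout female 2 (0.102 each). Cytochromes P450 were lost without wild-type female 2 (0.0634), knockout male 1 (0.0868) or wild-type male 2 (0.0952), and fatty acid synthesis without wild-type female 2 (0.365), knockout female 1 (0.184), knockout male 1 (0.129) or wild-type male 1 (0.124). Proliferation was lost without wild-type female 2 (0.17), knockout female 2 (0.143), knockout male 2 (0.162) or wild-type male 2 (0.0952). The interferon response was lost without wild-type female 1 (0.117), knockout female 2 (0.414), wild-type male 1 (0.644) or knockout male 2 (0.094). Macrophage markers were lost without wild-type female 1 (0.141), wild-type female 2 (0.0634), knockout female 2 (0.322), knockout male 1 (0.255) or wild-type male 1 (0.736). The acute phase was lost without wild-type female 2 (0.365), knockout female 2 (0.212), knockout male 1 (0.286) or wild-type male 2 (0.416). With quantile normalization the acute phase (0.0542) and macrophage markers (0.0521) did not pass. With the mean of a gene's probe sets fatty acid synthesis (0.0631), the acute phase and the interferon response (0.0543 each) and proliferation (0.0606) did not.

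Among the named genes, 6 had all knockout arrays on one side of both wild-type arrays in females and on the other side in males, and limma's test of the difference passed for 0 of them. Bik, Slc25a25, Ifna15 and Grik5 were named for a small p in this same test, so their opposite sides are no separate support. With 2 arrays per group such a split can arise by chance, and its share over all genes was not counted. The male minus female effect was -4.75 for Bik (adjusted p = 0.312; log2 2.69 in females, -2.06 in males), 2.47 for Slc25a25 (adjusted p = 0.312; -1.41, 1.06), 2.93 for Ifna15 (adjusted p = 0.559; -1.43, 1.50) and 3.01 for Grik5 (adjusted p = 0.559; -1.23, 1.78). It was -1.32 for Mgst1 (adjusted p = 0.689; 1.07, -0.26) and 1.84 for Xist (adjusted p = 0.736), which in males lay near the floor.

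Prm1, a gene of haploid sperm cells, was higher in 4 of 4 knockout arrays than in the wild-type arrays of their sex, including the females. RNA from haploid germ cells is argued against: the other 22 measured genes of a list of 30 such genes had a median log2 difference of 0.0516 (mean 0.0808, 95% interval -0.13 to 0.292) against 3.49 for Prm1, and 0 had an unadjusted p under 0.05. A Prm1 sequence carried by the targeting construct may account for the signal. It would act alike in both sexes, and the male minus female effect was -0.427 (SE 0.803, adjusted p = 0.963). The construct's sequence is not given in the sources used here, and genotype and construct cannot be told apart in this design, nor can a related transcript bound by the 1 family probe set of Prm1 be excluded.

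The genotype calls could come from 129SVJ variants that stay linked to the knocked-out gene on chromosome 2 rather than from the lack of Nrf2. Of the 10 other called genes, 0 lie on chromosome 2; 4 of them, Ctsc, Cyp2b9, Gdpd3 and Bag3, lie on chromosome 7, and the others on chromosomes 1, 3, 5, 11 and 16. Of 100000 random sets of 10 measured genes, 3.34% had as many on 1 chromosome, so variants of the mixed cross elsewhere in the genome, chromosome 7 included, stay open. Around Nfe2l2, 9 of the 200 nearest measured genes (4.50%) had an unadjusted p under 0.05, against 559 of 7087 (7.89%) on other chromosomes (odds ratio 0.55, 95% interval 0.246 to 1.07, two-sided Fisher exact p = 0.0819), so no excess near the gene was seen. Of the 18 splits of the arrays within the sexes, 1, the real one, gave 11 calls or more, and the highest other gave 0. The 18 splits are too few for a share under 0.05. Nearly all other splits also mix the genotypes on a side, so real genotype differences add to the spread there and hold the counts down. The splits therefore cannot decide whether the calls arose by chance. For the sex comparison, 1 of 18 splits, the real one, gave 119 calls or more, the highest other gave 0, and the same limits hold, with the sexes mixed.

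The fall of interferon, T and NK cell and macrophage lists in the knockout could come from wild-type male 1 alone, which had high immune transcripts. Without it the interferon and T and NK cell genes kept a median of -0.306 (interferon adjusted p = 0.000132, T and NK cells 0.00174), which argues against that array as the whole source, while the macrophage list went from -0.61 to -0.133 (adjusted p = 0.21), which is consistent with that array as its main source. An equally lower share of all cells other than hepatocytes was tested too. The T and NK cell markers had a mean of -0.40 (95% interval over genes -0.671 to -0.138). Of the other liver cell types, 1 list, neutrophils and mast cells (mean 0.23, 95% interval 0.015 to 0.45), lay wholly above them. It did so without wild-type male 1 too (-0.0229 to 0.699 against -0.747 to -0.172). These intervals take genes of the same 8 arrays as replicates and miss the spread between arrays, so they cannot decide the question. Per array, the neutrophil list's median ran from -0.306 to 0.505 in wild type and from -0.169 to 0.203 in knockout. The means of macrophage (-0.70), stellate (-0.30), endothelial (-0.28), cholangiocyte (-0.25) and erythroid markers (-0.21) were negative too. A lower share of non-hepatocyte cells, a change in neutrophils themselves, a lower interferon response or fewer lymphocytes in livers without Nrf2 stay open.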

How the results depend on the processing

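Leaving out wild-type female 1 and wild-type male 1 together, and crossing the wild-type replicate numbers, were chosen after seeing the data; the other alternatives were fixed in advance. Each was run, but not for every result. Lists were retested with quantile normalization, the replicate block (genotype contrasts), an estimated correlation, fry, the mean of probe sets and arrays left out. Those of male against female in wild type were retested only with an estimated correlation and fry. Signal over background limits the weakest genes: between 77.8% and 82.0% of probe sets exceeded the floor on an array. In fits that leave out 1 array, the lone array of its group is assumed to vary like the other groups.

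Named genes are counted here without those added only as list members or chosen after their values were seen. Genes named in advance are counted in the genotype average, or in the sex average for X and Y genes. Of the named genes past the threshold, 863 values under alternatives gave 605 on the same side of the threshold, 258 no longer past it and 0 of opposite direction. Of the named genes not past it, 727 values gave 692 on the same side, 29 past it and 6 of opposite direction. Of the lists past the threshold, 748 values gave 553 past it, 193 not past it and 2 of opposite direction. For the genotype average, the adjusted p of the Nrf2 target list ran from 9.15e-13 to 0.0549 over 14 alternatives, that of cholesterol synthesis from 6.42e-14 to 0.233 and that of the interferon response from 3.49e-12 to 0.233. For the difference between the sexes, that of fatty acid oxidation ran from 6.16e-14 to 0.197.

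Counts of probe sets past the threshold are compared with 11 for the genotype average, 0 in females, 14 in males, 0 for the difference between the sexes, 119 for the sex average and 30 for sex in wild type. With a pseudocount they were 25 for the genotype average, 3 in females, 31 in males and 51 for sex in wild type. With no filter they were 17 for the genotype average, 4 in females, 15 in males, 8 for the difference between the sexes and 45 for the sex average. With only the probe sets above the median level they were 23 for the genotype average, 2 in females, 29 in males, 179 for the sex average and 47 for sex in wild type, where fewer probe sets were tested. With robust variance they were 18 for the genotype average, 2 in females, 31 in males and 46 for sex in wild type. With no intensity trend they were 0 for the genotype average, 0 in males, 51 for the sex average and 16 for sex in wild type. At a threshold of 0.1 they were by construction higher: 18 for the genotype average, 1 in females, 30 in males, 224 for the sex average and 57 for sex in wild type. In males the count was 6 with arrays scaled to one median, 6 with array weights, 9 with the floor at the 10th percentile and 0 with the arrays of males alone, where fewer arrays were used. In females it was 3 with the floor at the 40th percentile. The genotype average gave 5 with an additive model and 4 with genotype alone. Without wild-type female 1 and wild-type male 1, which leaves fewer arrays, the counts were 0 for the genotype average, 0 in males, 18 for the sex average and 0 for sex in wild type. Apart from the changes named as following from the construction, the cause was not tested.

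Of the list tests of the genotype average, 16 passed, against 0 with an estimated correlation and 2 with fry, which tests each list without the other genes. In females 7 passed, against 0 and 0, in males 13, against 0 and 4, and for the sex average 8, against 1 and 5. For the difference between the sexes 10 passed, against 0 and 0, 6 with the mean of a gene's probe sets, and 4 to 10 when 1 array was left out. In females, leaving out 1 array gave 2 to 8 lists.

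Leaving out each array in turn gave 0 to 22 for the genotype average, 0 to 2 in females, 1 to 12 in males, 0 to 3 for the difference between the sexes, 26 to 78 for the sex average, 12 to 32 for sex in wild type and 12 to 21 lists, with fewer arrays in each fit. Gclm, with a main log2 difference of -0.00, gave 0.000202 with quantile normalization and -0.16 to 0.15 when 1 array was left out. Kdm5d, with a main sex difference of 0.11, gave -0.00334 without wild-type male 2, the lowest value when 1 array was left out, and 0.20 without wild-type male 1, the highest. The macrophage list, lower in males in the difference between the sexes, had an adjusted p from 1.06e-10 to 0.736 when 1 array was left out, and was of opposite direction without wild-type male 1 (adjusted p = 0.736) and without wild-type female 1 and wild-type male 1 (adjusted p = 0.586).

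With the replicate number as a block, the counts were 7 for the genotype average, 4 in males and 58 for the sex average. The deviations of arrays with the same number correlated between groups from -0.131 to 0.0762, so the numbers do not pair the arrays. With the wild-type numbers crossed, the sex average gave 89 and sex in wild type 32.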

Other observations

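The test of CAR targets in this part was planned before its result was seen.

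In knockout males, acute phase genes rose as a list, with 19 of 27 positive and a median log2 difference of 0.45 (camera adjusted p = 0.00611; adjusted p = 0.32 with an estimated correlation). In limma 0 of them passed over all genes tested and 3 adjusted over the list alone: Orm2, which encodes a plasma transport protein (log2 3.48, 11.2-fold), Saa3 (2.35, 5.11-fold) and Saa2 (2.12, 4.34-fold). The call was lost without knockout male 1 (adjusted p = 0.148) or wild-type male 2 (0.277). In knockout females the same list had a median of -0.08 (adjusted p = 0.946).

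Within wild type, males had higher values than females for carbonyl and ester metabolism (median 0.34, adjusted p = 0.00208; adjusted p = 0.207 with an estimated correlation), bile acid synthesis (0.42, 0.0351; adjusted p = 0.568 with an estimated correlation), male-biased genes (1.27, 8.31e-12; adjusted p = 0.207 with an estimated correlation) and complement and coagulation (0.22, 0.0352; adjusted p = 0.452 with an estimated correlation). They had lower values for fatty acid synthesis (-0.79, 3.04e-06; adjusted p = 0.208 with an estimated correlation), glucuronosyltransferases and sulfotransferases (-0.32, 0.00106; adjusted p = 0.452 with an estimated correlation) and proliferation (-0.39, 0.0352; adjusted p = 0.392 with an estimated correlation).

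In the average over both sexes, 25 of the 41 lists did not pass. Glutathione S-transferases had a median log2 difference of -0.04 (adjusted p = 0.0617), with 1 of 17 lower over all genes tested and 5 adjusted over the list alone. An adjusted p of 0.09 was reached by NADPH production (-0.04), amino acid metabolism and the urea cycle (-0.11), p53 and DNA damage (-0.14), erythroid cells (-0.30) and pericentral hepatocytes (-0.11, but 0.01 after quantile normalization). The circadian clock gave 0.18 (0.115), cholangiocytes -0.20 (0.134), fatty acid oxidation -0.06 (0.136), heat shock and ER stress 0.11 (0.155), neutrophils and mast cells 0.10 (0.432), and gluconeogenesis and glycolysis 0.09 (0.48). Fatty acid synthesis gave 0.01 with a mean of -0.05, bile acid synthesis -0.11 with a mean of 0.03, lipoproteins -0.09 with a mean of 0.03, and exocrine pancreas 0.16 with a mean of -0.11, so the median and the mean differed in sign. The same held for antioxidant enzymes (-0.07, mean 0.23), male-biased genes (-0.03, mean 0.18), periportal hepatocytes (-0.02, mean 0.04) and X- and Y-linked genes (-0.07, mean 0.01). Complement and coagulation gave -0.03, proliferation 0.08, glutathione synthesis and thioredoxin 0.05, muscle and fat 0.11, and B and plasma cells -0.05, while camera ranked the last of these up. The adjusted p of these 13 lists ran from 0.752 to 0.985, and antioxidant enzymes, lipoproteins, male-biased genes and periportal hepatocytes changed sign after quantile normalization.

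Among the macrophage markers, wild-type male 1 had the highest intensity of Marco, a scavenger receptor (9667, against at most 5877 on the other arrays), and the lowest of Clec4f, a Kupffer cell lectin (2200.4, against at least 4645).

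Since Nr1i3, which encodes the receptor CAR, was lower in knockout males, the hypothesis that target genes of CAR are lower there was tested on 12 measured genes outside the Nrf2 list, 11 of which are also in a fixed list. In males, 7 of 12 were negative with a median of -0.09 (camera p = 0.0965; p = 0.301 with an estimated correlation; fry p = 0.29), and Cyp2b10, the classical target, gave -1.23 (adjusted p = 0.392). A camera p above 0.05 had been set in advance as the value that would exclude the hypothesis, but with 12 genes such a p cannot rule out a smaller decrease, so the data may hold one and the question stays open. Averaged over both sexes, 9 of 12 were negative (camera p = 0.0322; p = 0.201 with an estimated correlation).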
